A study of Mus musculus with 12 samples.

How the data were processed

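Gene expression was measured by RNA sequencing in the ventral hippocampus of mice, with 12 libraries in 4 groups of 3. The groups were control mice, mice exposed to CSDS, mice given AAV8-eGFP and exposed to SSDS (SSDS-GFP), and mice with hepatic ACOT12 knockdown exposed to SSDS (SSDS-shACOT12). In this field CSDS and SSDS usually stand for chronic and subthreshold social defeat stress; the labels give only the abbreviations. Libraries were made from 1 µg of total RNA with the NEBNext Ultra RNA kit, whose name does not mark strand, so antisense genes cannot be told apart. Per the labels, reads were aligned with HISAT2 2.0.5 to mm10 and counted per gene with featureCounts 1.5.0-p3, and DESeq2 was used with no version given. The strand setting, the annotation release and any filter were not stated.

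The deposited counts are raw whole numbers per gene for 54532 genes, of which 32777 had a count in some library. The deposited FPKM values were scaled by the authors by gene length in kilobases and by a library size that was 0.958 to 1.06 times the count total; how that factor was made is not stated. Gene length is given per the file headers, in bases (a unit other than expression). The total per library ran from 14656714 to 17694570 counts. For 27 genes whose symbols had been turned into dates, the symbol was restored by gene ID from GENCODE release M21, which held 54495 of the IDs, 98.3% of all IDs with the same coordinates.

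All comparisons used the counts. Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 16915 genes, and libraries were scaled by TMM. Expression levels are CPM of the scaled library, from the cpm function of edgeR. A quasi-likelihood model with group as the only factor was fitted to all 12 libraries, and each contrast was tested with 2-sided Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values of genes are from this edgeR test unless DESeq2 or limma is named. The contrasts were CSDS against control, SSDS-shACOT12 against SSDS-GFP, SSDS-GFP against control, and the difference of the 2 former contrasts. Errors of log2 fold changes are standard errors from the model, and errors of CPM are SD over 3 libraries.

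Before the data were examined, 39 gene lists were fixed that hold markers of the cell types and regions the tissue could contain and members of pathways related to stress, inflammation and acetyl-CoA. The 38 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values at a preset correlation of 0.01, with adjustment over the lists. The test was repeated with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction. For each list, members were also counted with p adjusted over the list alone.

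The genes named were chosen by a rule fixed at the same time. The rule took the largest changes among called genes with a mean log2 CPM of at least 1 (up to 10 each way, or 5 for SSDS-GFP against control), where too few were called the 10 genes with the smallest p, up to 4 members of each called list (2 for SSDS-GFP against control), and a fixed set of genes of acetyl-CoA metabolism, inflammation, glia and plasticity. Of that set, Tnf and Il6 had too few counts to be tested.

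The alternatives chosen in advance were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 50 counts in 3 libraries, only the 6 libraries compared, the replicate number as a block, each library left out, limma-trend on log2 FPKM with 0.1 or 1 added, a minimum absolute log2 fold change of 1, limma-voom for the difference of effects, and Spearman correlation. Chosen after seeing the data were the replicate number as a block among the SSDS libraries alone, leaving out mitochondrial genes, limma-voom with library quality weights, removing each library's trend with gene length (lowess, span 0.3), and leaving out SSDS-GFP 3 with SSDS-shACOT12 2.

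The labels do not say what a replicate number shares. The deviations from the group means of SSDS-GFP and SSDS-shACOT12 libraries of the same number correlated at 0.196, 0.419 and 0.353. All lay over the bound of 0.1, so these 2 groups were also compared in pairs. Of all 18 pairs of the same number, 5 lay over that bound. Pairs of different number passed it too, with up to 0.279 for Control 2 with SSDS-GFP 3. The median correlation was -0.015 at the same number and -0.031 at other numbers. The bound by itself therefore does not mark a shared structure.

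The tests were tried on simulated data of this size, with the spread of each gene estimated over all groups. For CSDS against control, 1.5% of genes changed 1.5-fold, 53.7% of genes changed 2-fold and 80.3% of genes changed 4-fold were recovered, with 3 false calls among 16715 unchanged genes. For SSDS-shACOT12 against SSDS-GFP the shares were 7.5%, 53.7% and 95.5%, with 5 false calls. A simulated shift of 0.30 in 1 list was called by camera in both contrasts, with 0 other lists called. The simulated genes were drawn independently of each other, each with the same spread in all groups. The simulation therefore gives no rate of false list calls for real genes that vary together. The real SSDS libraries varied more than the others, so recovery for knockdown may be lower than these shares. Between the contrasts the simulations differed only in library sizes and random draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.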

Results

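The transcriptome of the ventral hippocampus was profiled in control mice, mice exposed to CSDS, and mice exposed to SSDS after either AAV8-eGFP or hepatic knockdown of ACOT12, an acetyl-CoA thioesterase. Each group had 3 libraries, with totals from 14656714 counts (SSDS-GFP 1) to 17694570 (CSDS 2). The labels do not say that replicates are separate animals, so p-values measure the spread between these libraries.

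Acot12 itself (ENSMUSG00000021620, chromosome 13, 91741512 to 91786148, mm10) was near the detection limit in the hippocampus, with 3 to 14 counts per library. It was measured at 0.796, 0.649 and 0.535 CPM in the 3 control libraries, 0.752, 0.406 and 0.845 in CSDS, 0.217, 0.525 and 0.400 in SSDS-GFP, and 0.433, 0.191 and 0.248 in SSDS-shACOT12. The log2 fold change between SSDS-shACOT12 and SSDS-GFP was -0.39 ± 0.52 (SE, adjusted p = 0.851). Because the knockdown was hepatic, this level checks neither the knockdown nor the labels.

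The SSDS libraries varied more than the others. The median SD of log2 CPM over genes was 0.155 in control, 0.157 in CSDS, 0.246 in SSDS-GFP and 0.308 in SSDS-shACOT12 (n = 3 each). Mitochondrially encoded genes took 3.23% of counts in SSDS-shACOT12 1 and 4.31% in SSDS-shACOT12 3, against 6.31% to 9.24% in the other libraries. The highest share was in SSDS-shACOT12 2. On the first principal component of log2 CPM, which held 31.3% of the variance, SSDS-shACOT12 3 (63.1), SSDS-shACOT12 1 (37.4) and SSDS-GFP 3 (35.7) lay apart from the other libraries, whose highest score was 5.82 in SSDS-GFP 1.

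**Figure D1:**
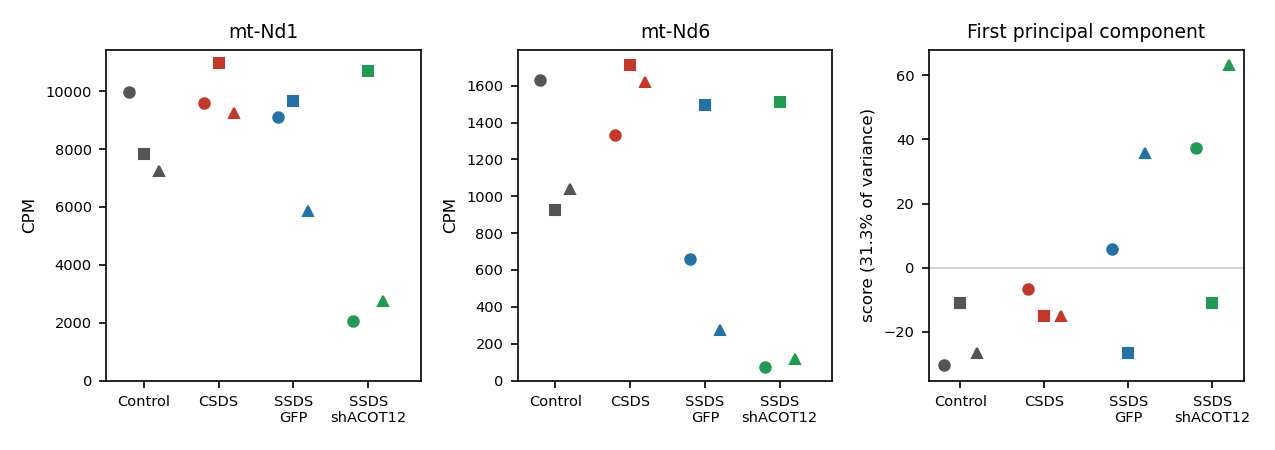
CPM of the mitochondrially encoded genes mt-Nd1 and mt-Nd6 and the score on the first principal component (31.3% of variance) in each library, by group; circles, squares and triangles are replicates 1, 2 and 3. SSDS-GFP 3, SSDS-shACOT12 1 and SSDS-shACOT12 3 had the highest component scores, and their mt-Nd6 levels of 272, 71.8 and 118 CPM were the lowest.

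The contrast of CSDS with control asks what repeated social stress changes in this region. Red blood cell transcripts were higher in CSDS. Hbb-bs, a beta chain of haemoglobin (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096), averaged 62.2 ± 9.95 CPM (SD, n = 3) in control and 199 ± 24.8 CPM in CSDS, a log2 fold change of 1.68 ± 0.25 (SE). Ttr, the thyroid hormone carrier that choroid plexus makes in large amounts (ENSMUSG00000061808, chromosome 18, 20665250 to 20674324), had 504, 141 and 7.91 CPM in the control libraries and 1.03 to 3.63 CPM in CSDS. Neither gene passed the test over all genes, with adjusted p = 0.207 for Hbb-bs and 0.502 for Ttr. As groups of genes fixed in advance, blood cell, chaperone, respiratory chain and ribosomal protein lists rose, and choroid plexus, ependymal and dentate gyrus lists fell. These are 7 of the 10 lists that camera called, and none was called with an estimated correlation (smallest adjusted p = 0.443). The mean scores of the choroid plexus and ependymal lists overlapped between control and CSDS libraries. Of the 10 splits of these 6 libraries into 3 and 3, looked at after the data were seen, 8 gave at least 10 called lists, the real split among them. The number of called lists therefore does not set the real grouping apart.

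No single gene passed: edgeR called 0 of 16915 genes, with 993 at an unadjusted p under 0.05 (484 higher and 509 lower in CSDS). The DESeq2 Wald test called 6 genes, of which Hbb-bs (adjusted p = 3.6e-07), Hba-a1, Hbb-bt and Bglap3 were higher and Ttr (4.9e-05) and Kcna1 were lower. Limma-trend on FPKM called 0 with either added constant, and limma-voom with quality weights, chosen after seeing the data, called 34. The edgeR fit called 132 genes with no filter. On the 6 libraries alone it called 84, with 2535 at an unadjusted p under 0.05. The main fit estimates the spread over all 12 libraries, and the SSDS libraries varied more. Their median SD was 0.246 and 0.308, against 0.155 in control and 0.157 in CSDS. The count of 0 may therefore partly reflect libraries outside this contrast. Without Control 3, a single gene passed, Ttr, with adjusted p = 0.0172.

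Besides Hbb-bs and Ttr, the genes with the smallest p included other haemoglobin chains, ion channel genes and a gene for a stress-induced inhibitor of mTOR signalling. Hba-a1 averaged 32.1 ± 2.69 CPM in control and 117 ± 9.57 in CSDS, and Hbb-bt 5.52 ± 1.74 and 20.4 ± 3.33 (SD, n = 3). Kcna1, a voltage-gated potassium channel, averaged 49.2 ± 12.3 CPM in control and 21.9 ± 5.14 in CSDS, with a log2 fold change of -1.17 ± 0.24. Cacng5, an auxiliary subunit of AMPA receptors, averaged 13.7 ± 1.34 and 6.33 ± 1.10 CPM. Ddit4l, the mTOR inhibitor, averaged 7.10 ± 1.55 and 15.5 ± 4.42 CPM. Bglap3, Npsr1 and the pseudogene Rps18-ps3 were also higher, with log2 fold changes of 4.08, 3.92 and 1.89, but averaged under 3 CPM in both groups. Reads of haemoglobin paralogs and of Rps18-ps3 cannot be assigned with certainty. Among these 10 genes the adjusted p ran from 0.207 to 0.849.

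**Figure D2:**
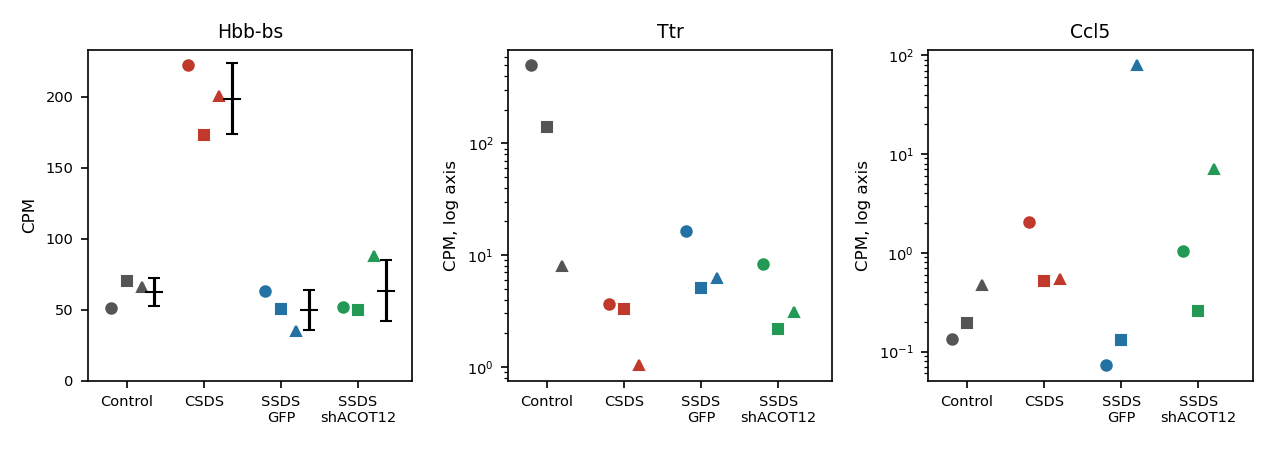
CPM of Hbb-bs (linear axis), Ttr and Ccl5 (log axes) in each library, by group; circles, squares and triangles are replicates 1, 2 and 3, and bars on Hbb-bs give mean and SD (n = 3). Hbb-bs lies between 173 and 222 CPM in CSDS and between 35.1 and 87.8 CPM in the other libraries, Ttr reaches 504 CPM in Control 1 and 141 CPM in Control 2, and Ccl5 reaches 79.5 CPM in SSDS-GFP 3.

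Of the 38 lists, camera called 10 in CSDS against control, 6 higher and 4 lower; with an estimated correlation 0 were called (smallest adjusted p = 0.443) and fry called 0. The blood cell list rose, with 7 of 9 measured members higher and a median log2 fold change of 1.32 (adjusted p = 1.4e-08; adjusted p = 0.443 with an estimated correlation). Over all genes 0 of its members passed; adjusted over the list alone 5 rose and 1 fell, the latter being Lcn2, a neutrophil granule and reactive astrocyte gene. The heat shock and unfolded protein response list rose, with 26 of 30 members higher and a median of 0.23 (adjusted p = 1.4e-08; adjusted p = 0.443 with an estimated correlation); 0 members rose over all genes and 5 adjusted over the list alone. Its members include Hspb1, a small heat shock protein, at 3.35 ± 1.02 CPM in control and 6.32 ± 1.13 in CSDS, and Creld2, a factor of the endoplasmic reticulum, at 12.7 ± 1.35 and 18.1 ± 0.21 CPM (SD, n = 3).

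Nuclear genes of oxidative phosphorylation rose in CSDS, with 74 of 81 higher and a median of 0.27 (adjusted p = 5.2e-16; adjusted p = 0.834 with an estimated correlation). Cytoplasmic ribosomal protein genes also rose, with 75 of 81 higher and a median of 0.19 (adjusted p = 1.3e-10; adjusted p = 0.914 with an estimated correlation). In each list 0 members passed over all genes and 0 adjusted over the list alone. Ndufab1, the mitochondrial acyl carrier protein, averaged 44.6 ± 2.28 CPM in control and 58.7 ± 5.24 in CSDS, and Rpl35 averaged 126 ± 9.35 and 167 ± 10.4 CPM (SD, n = 3). Short genes were higher in CSDS as a whole: the median log2 fold change was 0.14 in the shortest of 8 bins of tested genes by length and -0.09 in the longest.

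Choroid plexus genes fell in CSDS, with 13 of 15 lower and a median of -0.74 (adjusted p = 4.7e-05; adjusted p = 0.443 with an estimated correlation); 1 member, Ttr, fell adjusted over the list alone and 0 over all genes. Without Control 1 the median was -0.36. Enpp2, also known from myelin, had 272 CPM in Control 1 and 84.4 to 118 CPM in the other control and CSDS libraries. Ependymal genes fell, with 14 of 15 lower and a median of -0.48 (adjusted p = 9e-06; adjusted p = 0.834 with an estimated correlation), and 0 passed singly by either adjustment. This call was lost without CSDS 3 (median -0.12, adjusted p = 0.487), and the median was -1.32 without CSDS 2, -0.74 without CSDS 1 and -0.72 without Control 3. Tekt4, a protein of ciliary microtubules, averaged 1.56 ± 1.13 CPM in control and 0.50 ± 0.11 in CSDS (SD, n = 3).

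Dentate gyrus genes fell in CSDS, with 15 of 18 lower and a median of -0.34 (adjusted p = 2.3e-05; adjusted p = 0.443 with an estimated correlation). Of its members 0 fell over all genes and 1, Pdzd2, adjusted over the list alone. The mean score of the list was 0.34, 0.27 and 0.45 in the control libraries and at most 0.11 in any other library. SSDS-GFP is set against the same control libraries, so a trait of these libraries cannot be told apart from an effect of stress. Pdzd2 averaged 65.5 ± 3.74 CPM in control and 44.7 ± 3.64 in CSDS, and Stxbp6, a regulator of vesicle fusion, 171 ± 26.7 and 123 ± 5.01 (SD, n = 3). Ventral hippocampus markers rose, with 14 of 20 higher and a median of 0.52 (adjusted p = 0.011; adjusted p = 0.967 with an estimated correlation), a call lost without Control 3 (adjusted p = 0.120). Nts, the neuropeptide neurotensin, was at 3.01 ± 1.80 CPM in control and 11.1 ± 6.59 in CSDS. Genes of inhibitory neurons and GABA synapses rose, with 21 of 29 higher and a median of 0.16 (adjusted p = 0.011; adjusted p = 0.834 with an estimated correlation), which was lost without Control 1 (median 0.09, adjusted p = 0.143) or CSDS 2 (adjusted p = 0.102). Pvalb, a marker of fast-spiking interneurons, averaged 37.3 ± 6.23 and 53.1 ± 6.88 CPM. Glucocorticoid-responsive genes fell, with 23 of 27 lower and a median of -0.32 (adjusted p = 0.0037; adjusted p = 0.863 with an estimated correlation), but without Control 2 the median was -0.03 (adjusted p = 0.828). Plin4, a lipid droplet protein, had 42.4 CPM in Control 2 against 11.8 and 1.61 CPM in the other control libraries. In these last 3 lists 0 members passed by either adjustment.

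Lists of inflammation and glia did not pass in CSDS. The median log2 fold change was 0.04 for inflammatory cytokines and NF-kB (adjusted p = 0.903), 0.05 for homeostatic microglia (0.510), 0.04 for activated microglia (0.866; mean -0.02), -0.03 for interferon response (0.735) and 0.06 for reactive astrocytes (0.829; mean -0.24 and the test also negative). It was 0.05 for acetyl-CoA and acetate metabolism (0.735; mean -0.01) and 0.003 for histone acetylation (0.866; mean and test negative). Acss2, which makes acetyl-CoA from acetate, averaged 50.8 ± 2.98 CPM in control and 52.6 ± 1.45 in CSDS (SD, n = 3; log2 fold change 0.05 ± 0.11). Acss1 and Acly differed by 0.12 ± 0.11 and 0.07 ± 0.12. Among Il1b, Aif1, Itgam, Cd68, Nlrp3, Tlr4, Gfap, Bdnf, Fos and Fkbp5, log2 fold changes ran from -0.32 (Tlr4) to 0.53 (Fos), with adjusted p of 0.922 or more.

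The contrast of SSDS-shACOT12 with SSDS-GFP asks what hepatic ACOT12 knockdown changes in the hippocampus of mice under SSDS. Mitochondrially encoded protein genes fell as a list with knockdown (13 of 13 lower, camera adjusted p = 2e-06, and adjusted p = 0.984 with an estimated correlation). SSDS-shACOT12 2 did not share this fall. The mean score of the list was -2.12, 0.72 and -1.48 in SSDS-shACOT12 1, 2 and 3, against 0.36, 0.90 and -0.50 in SSDS-GFP 1, 2 and 3. Interferon response and dentate gyrus genes also fell (26 of 29 and 14 of 18 lower, adjusted p = 2e-04 and 1e-04; adjusted p = 0.984 with an estimated correlation for both). Tdo2, a tryptophan-degrading enzyme on the dentate gyrus list (ENSMUSG00000028011, chromosome 3, 81957090 to 81976202), averaged 10.5 ± 1.39 CPM in SSDS-GFP and 4.2 ± 2.9 in SSDS-shACOT12 (SD, n = 3), a log2 fold change of -1.31 ± 0.37 (SE, adjusted p = 0.803). Several of the list calls changed when 1 library was left out, and the values without it are given beside each list.

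No gene passed in this contrast: edgeR called 0, with 766 of 16915 at an unadjusted p under 0.05 (312 higher and 454 lower with knockdown). DESeq2, limma-trend on FPKM and limma-voom with quality weights also called 0, and edgeR with no filter called 108. On the 6 SSDS libraries alone edgeR called 0, with 183 at an unadjusted p under 0.05. Without SSDS-shACOT12 2 the count was 985 (190 higher and 795 lower), and without SSDS-shACOT12 1 it was 2. With SSDS-GFP 3 and SSDS-shACOT12 2 both left out it was 2947, but those libraries were chosen for their values and leave 2 against 2.

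The 10 genes with the smallest p all had adjusted p = 0.803. Crhbp, which binds corticotropin-releasing hormone, averaged 24.8 ± 1.95 CPM in SSDS-GFP and 37.6 ± 8.27 in SSDS-shACOT12 (SD, n = 3), with a log2 fold change of 0.60 ± 0.16. Scube1, a secreted glycoprotein, averaged 9.92 ± 1.27 and 16.3 ± 3.58 CPM. Both passed without SSDS-shACOT12 2 (adjusted p = 0.0448 and 0.0274), as did Pbld2, mt-Tm, Gm20186, Gm21887 and Gm4544 (0.0267 to 0.0446). With any other SSDS library left out, edgeR called 0 genes, or 2 without SSDS-shACOT12 1. These calls, and those given below for the same run, depend on leaving out SSDS-shACOT12 2. That library correlated more with SSDS-GFP 1 and 2 than with its own group. Amd2, Pbld2 and the mitochondrial tRNA gene mt-Tm had log2 fold changes of -1.95 ± 0.46, 1.44 ± 0.38 and -1.48 ± 0.30. The other 5 were gene models or noncoding genes (Gm20186, Gm21887, Gm4544, A730035I17Rik and Gm11451), with log2 fold changes from -2.88 to 2.45, whose reads may be shared with other loci.

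Camera called 5 lists in this contrast, 1 higher and 4 lower; with an estimated correlation 0 were called (smallest adjusted p = 0.984) and fry called 0. In each of the 5 lists 0 members passed over all genes and 0 adjusted over the list alone. With the replicate number as a block among the SSDS libraries, chosen after seeing the data, 9 lists were called, 2 higher and 7 lower, and with an estimated correlation 0 (smallest adjusted p = 0.920). They were the 5 lists and those of inflammatory cytokines and NF-kB (median -0.22, adjusted p = 0.0014), antigen presentation (-0.31, 0.0028), oligodendrocytes and myelin (-0.14, 0.0446) and nuclear oxidative phosphorylation (0.09, 0.0177). On the 6 SSDS libraries alone 10 lists were called. With SSDS-GFP 3 and SSDS-shACOT12 2 both left out, 4 lists were called, and 0 with an estimated correlation (smallest adjusted p = 0.681). Of the 5 lists, mitochondrially encoded genes were called in that run (median -2.54, adjusted p = 6.8e-10), and interferon response (0.15, 0.806), dentate gyrus (-0.19, 0.560), cholesterol and fatty acid synthesis (0.30, 0.138) and heat shock genes (-0.06, 0.0811) were not. The other 3 were oligodendrocyte and myelin (-0.34, 0.0048), nuclear oxidative phosphorylation (0.22, 0.0471) and ribosomal protein genes (0.17, 0.0126). Inflammatory cytokine and NF-kB genes (0.26, 0.560) and antigen presentation genes (0.89, 0.0585) had positive medians in that run and were not called. Of the 12 libraries, SSDS-GFP 3 had the highest mean score of both lists (1.3 and 1.7, log2 relative to the mean of all libraries). Mitochondrially encoded protein genes fell, with 13 of 13 lower and a median of -0.60 (adjusted p = 2e-06; adjusted p = 0.984 with an estimated correlation). The median was -2.04 without SSDS-shACOT12 2, -0.26 without SSDS-shACOT12 1, -0.35 without SSDS-shACOT12 3 and -0.36 without SSDS-GFP 2, and the call held in each case; with the block it was -1.04. mt-Co1, a subunit of cytochrome c oxidase, had 25158 ± 2685 CPM in SSDS-GFP and 17946 ± 4876 in SSDS-shACOT12 (SD, n = 3), and passed without SSDS-shACOT12 2 (adjusted p = 0.0282), as did mt-Atp8 (0.0293).

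Interferon response genes fell with knockdown, with 26 of 29 lower and a median of -0.59 (adjusted p = 2e-04; adjusted p = 0.984 with an estimated correlation). Without SSDS-GFP 3 the median was 0.04 (adjusted p = 0.970), and without SSDS-shACOT12 2 the adjusted p was 0.0913. Ifit1, an antiviral effector, was at 3.83 and 3.22 CPM in SSDS-GFP 1 and 2, 7.32 CPM in SSDS-GFP 3, and 1.81 ± 0.20 CPM in SSDS-shACOT12 (SD, n = 3). Cholesterol and fatty acid synthesis genes rose, with 26 of 31 higher and a median of 0.24 (adjusted p = 0.0022; adjusted p = 0.984 with an estimated correlation). Without SSDS-shACOT12 3 the median was -0.0025 (adjusted p = 0.869), and without SSDS-GFP 3 the adjusted p was 0.15.

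Dentate gyrus genes fell with knockdown, with 14 of 18 lower and a median of -0.27 (adjusted p = 1e-04; adjusted p = 0.984 with an estimated correlation). The median was -0.41 without SSDS-shACOT12 1, -0.16 without SSDS-GFP 2 and -0.17 without SSDS-shACOT12 2, and the call was lost in the last case (adjusted p = 0.498). SSDS-shACOT12 2 had the lowest mean score of dentate gyrus genes of the 12 libraries (-0.77, log2 relative to the mean of all libraries), the highest of ventral hippocampus markers (1.05) and the lowest of dorsal hippocampus markers (-0.55), a list that shares Lct and Tdo2 with the dentate gyrus list. Calb1, a calcium buffer of granule cells, averaged 174 ± 28.0 CPM in SSDS-GFP and 114 ± 55.5 in SSDS-shACOT12 (SD, n = 3), with adjusted p = 0.0279 without SSDS-shACOT12 2. Heat shock and unfolded protein response genes fell, with 24 of 30 lower and a median of -0.14 (adjusted p = 0.0054; adjusted p = 0.984 with an estimated correlation). This was lost without SSDS-GFP 1 (median -0.06, adjusted p = 0.174), SSDS-shACOT12 1 (0.0677) or SSDS-shACOT12 2 (0.0659). Manf, a secreted factor of the endoplasmic reticulum stress response, averaged 83.5 ± 5.76 and 67.7 ± 5.54 CPM. The number of called lists was 8 without SSDS-GFP 1, 14 without SSDS-GFP 2, 12 without SSDS-shACOT12 1 and 11 without SSDS-shACOT12 3.

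Apart from interferon response, the lists of inflammation and glia named here did not pass with knockdown when no block was used. The median was -0.34 for inflammatory cytokines and NF-kB (18 of 24 lower, adjusted p = 0.0729), 0.03 for homeostatic microglia (0.919; mean and test negative), -0.01 for activated microglia (0.970), -0.54 for antigen presentation (0.290), 0.07 for acetyl-CoA and acetate metabolism (0.302) and 0.01 for histone acetylation (0.829). Gfap, the astrocyte intermediate filament gene, had 1192 CPM in SSDS-shACOT12 3 and 221 to 396 CPM in the other 5 SSDS libraries, with a log2 fold change of 1.00 ± 0.43 (adjusted p = 0.803, or 0.0310 without SSDS-shACOT12 2) that was 0.04 without SSDS-shACOT12 3. Tlr4 had -1.32 ± 0.54 and Cd68 0.60 ± 0.33, both with adjusted p = 0.803. Il1b had 13.5 CPM in SSDS-GFP 3 and 0 to 2.48 CPM in the other SSDS libraries, with a log2 fold change of -2.17 ± 1.31 that was 3.74 without SSDS-GFP 3. Bdnf and Fos had 0.80 ± 0.49 and 0.55 ± 0.46, and without SSDS-shACOT12 3 both were negative (-0.24 and -0.36). Aif1, Itgam, Nlrp3, Fkbp5, Acss1, Acss2 and Acly ran from -0.24 (Nlrp3) to 0.22 (Acss2), with adjusted p of 0.803 or more.

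The contrast of SSDS-GFP with control changes both the stress and the virus, so it cannot part them. Chaperone genes of the endoplasmic reticulum rose in the SSDS-GFP mice, and 13 genes in all passed as higher. Hspa5, the main chaperone of that compartment, also called BiP (ENSMUSG00000026864, chromosome 2, 34771970 to 34777547), averaged 171 ± 1.89 CPM in control and 404 ± 24.9 in SSDS-GFP (SD, n = 3), a 2.37-fold rise (adjusted p = 0.0028). Sdf2l1 (ENSMUSG00000022769, chromosome 16, 17130138 to 17132383) averaged 9.64 ± 0.47 and 27.3 ± 3.08 CPM, a 2.82-fold rise (adjusted p = 0.0013). Hspb1 (ENSMUSG00000004951, chromosome 5, 135887919 to 135889563) rose 3.48-fold, from 3.35 ± 1.02 to 11.7 ± 1.2 CPM (adjusted p = 0.0070). The level of Hspa5 was 222 ± 43.1 CPM in CSDS and 359 ± 20.1 in SSDS-shACOT12.

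**Figure D3:**
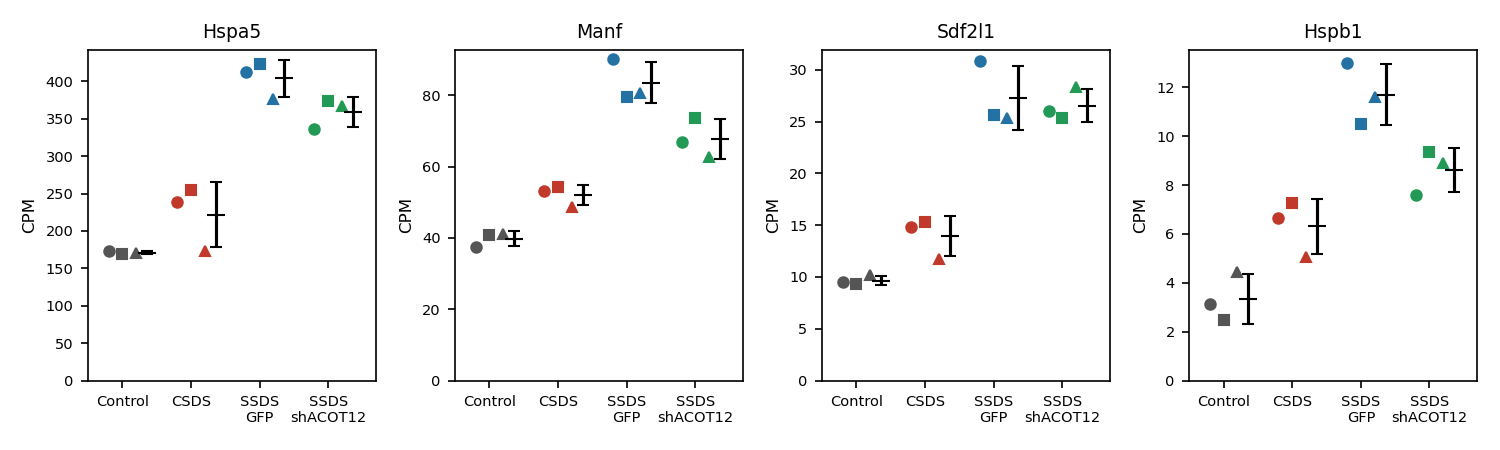
CPM of Hspa5, Manf, Sdf2l1 and Hspb1 in each library, by group, on linear axes from 0; circles, squares and triangles are replicates 1, 2 and 3, and bars give mean and SD (n = 3). For Hspa5 the 6 SSDS libraries lie between 336 and 423 CPM and the 6 control and CSDS libraries between 170 and 254 CPM.

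In SSDS-GFP against control 16 genes passed, 13 higher and 3 lower. Besides Hspa5, Sdf2l1 and Hspb1, the genes that rose were Pdia4, a disulphide isomerase, Manf, Calr, Creld2, the transcription factor Xbp1, the co-chaperone Dnajb1, P4ha1, Med20, Cdk2ap2 and the phosphatase gene Dusp1. Pdia4 had a log2 fold change of 1.15 ± 0.13 and Manf averaged 39.8 ± 2.03 and 83.5 ± 5.76 CPM (adjusted p = 0.0028 for both), and Dnajb1 1.08 ± 0.14 (adjusted p = 0.0069). Zfp46, a zinc finger gene, fell from 60.6 ± 5.32 to 28.2 ± 2.77 CPM (adjusted p = 0.0088), Adgrf5, an adhesion receptor of endothelium, from 46.4 ± 4.56 to 27.4 ± 2.13 CPM (adjusted p = 0.044), and Gab3 was the other gene that fell. DESeq2 called 527 genes, among them 15 of the 16. The count was 4 without Control 1 or without SSDS-GFP 1, 8 without Control 3, and 10 without Control 2 or without SSDS-GFP 3. Sdf2l1, Hspa5, Pdia4 and Manf passed in each of those runs, Hspb1 and Dnajb1 failed without Control 1 (adjusted p = 0.0892 for both) and without SSDS-GFP 1 (0.0667 for both), and Zfp46 also failed in these runs and without Control 3 (0.0506). Adgrf5 failed in all 6 runs (adjusted p from 0.0514 to 0.320) and Dusp1 in 5 of them (0.148 to 0.277).

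Camera called 8 lists, 6 higher and 2 lower, in SSDS-GFP against control; with an estimated correlation 0 were called (smallest adjusted p = 0.0584), and fry called 1, the heat shock list. Heat shock and unfolded protein response genes rose, with 30 of 30 higher and a median of 0.68 (adjusted p = 4.5e-27; adjusted p = 0.0584 with an estimated correlation; 2.7e-04 with fry); 9 members rose over all genes and 22 adjusted over the list alone. Immediate early genes, which neuronal activity induces, rose, with 28 of 30 higher and a median of 0.68 (adjusted p = 1.5e-09; adjusted p = 0.580 with an estimated correlation). Of its members 1, Dusp1, rose over all genes and 13 adjusted over the list alone. The mean score of the list was 0.05 to 0.87 in all SSDS libraries and -0.60 to -0.18 in control and CSDS. SSDS, the virus and a difference of handling or batch therefore cannot be told apart for this list. Egr2 averaged 0.95 ± 0.46 CPM in control and 5.33 ± 2.78 in SSDS-GFP (SD, n = 3, adjusted p = 0.107). Nuclear oxidative phosphorylation genes rose, with 79 of 81 higher and a median of 0.45 (adjusted p = 3.7e-25; adjusted p = 0.604 with an estimated correlation); 0 rose over all genes and 41 adjusted over the list alone. Ribosomal protein genes rose, with 78 of 81 higher and a median of 0.42 (adjusted p = 1.5e-24; adjusted p = 0.604 with an estimated correlation); 0 rose over all genes and 48 adjusted over the list alone. Cox7b, a cytochrome c oxidase subunit, averaged 135 ± 16.6 and 221 ± 22.2 CPM, and Rpl39 125 ± 5.74 and 188 ± 18.3 CPM. Short genes were higher here too, with a median log2 fold change of 0.20 in the shortest bin and -0.14 in the longest.

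**Figure D4:**
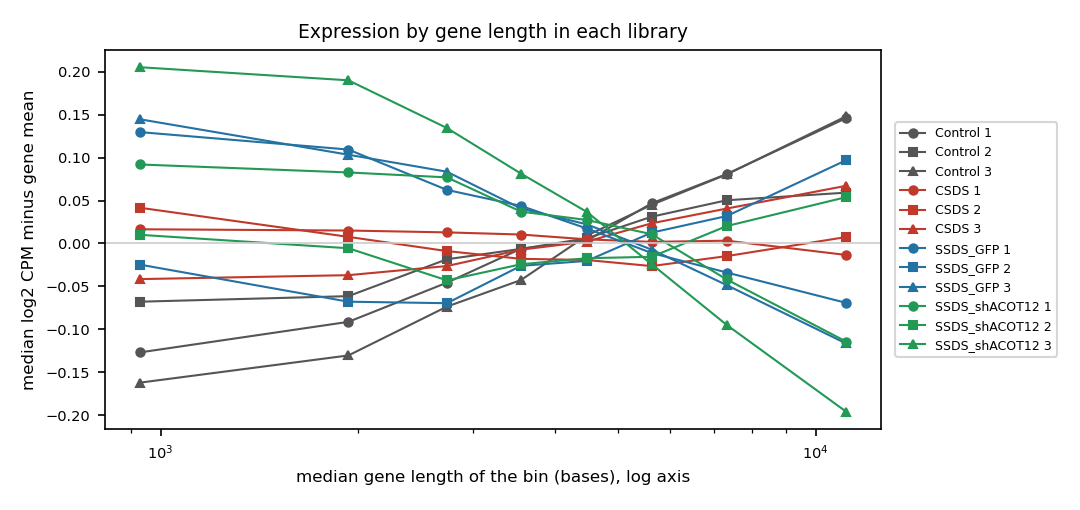
Median difference of log2 CPM from each gene's mean over the 12 libraries, by library, in 8 bins of genes ordered by gene length (bases, log axis); colours give the groups and symbols the replicates. In the shortest bin the control libraries lie at -0.13, -0.07 and -0.16 and SSDS-shACOT12 3 at 0.21, and in the longest bin this order is turned.

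Endothelial and blood-brain barrier genes fell in SSDS-GFP, with 16 of 21 lower and a median of -0.29 (adjusted p = 0.0021; adjusted p = 0.604 with an estimated correlation); 0 fell over all genes and 4 adjusted over the list alone. Pecam1, an adhesion molecule of endothelial junctions, averaged 22.8 ± 1.21 CPM in control and 13.3 ± 2.40 in SSDS-GFP (SD, n = 3, adjusted p = 0.116). Dentate gyrus genes fell, with 13 of 18 lower and a median of -0.38 (adjusted p = 7.2e-04; adjusted p = 0.604 with an estimated correlation); 0 fell over all genes and 2 adjusted over the list alone. With each library's trend with gene length removed the median was -0.19 (adjusted p = 0.0150). Pdzd2 was at 39.5 ± 2.10 CPM in SSDS-GFP. Ventral hippocampus markers rose, with 17 of 20 higher and a median of 0.56 (adjusted p = 0.0107; adjusted p = 0.890 with an estimated correlation). This was lost without Control 3 (adjusted p = 0.061) or SSDS-GFP 3 (median 0.34, adjusted p = 0.121), and the median was 0.89 without Control 2. Resp18, a neuroendocrine gene, averaged 27.8 ± 11.1 and 72.0 ± 32.6 CPM. Inflammatory cytokine and NF-kB genes rose, with 21 of 24 higher and a median of 0.48 (adjusted p = 0.0337; adjusted p = 0.890 with an estimated correlation), but without SSDS-GFP 3 the median was 0.07 (adjusted p = 0.655), and on the 6 libraries alone the list was not called (0.103). With SSDS-GFP 3 and SSDS-shACOT12 2 both left out, this list was lost (0.06, adjusted p = 0.631) and those of interferon response (-0.34, 0.0039), antigen presentation (-0.76, 0.0050), oligodendrocytes and myelin (0.15, 0.0039) and mural cells (-0.23, 0.0161) were called, none of them with an estimated correlation (adjusted p from 0.860 to 0.876). Ccl5, a chemokine, had 79.5 CPM in SSDS-GFP 3 and 0.072 and 0.13 CPM in SSDS-GFP 1 and 2, with a log2 fold change of 6.57 ± 2.03 that was -1.34 without SSDS-GFP 3. In these last 2 lists 0 members passed by either adjustment.

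The knockdown effect under SSDS and the CSDS effect, which share no library, were then set side by side. Across the 16915 genes, which are not independent replicates, their log2 fold changes had a Pearson correlation of 0.012 and a Spearman correlation of 0.051, and 53.0% of genes had the same sign. At an unadjusted p under 0.05 in both contrasts, 10 genes were higher in both (8.93 for independent lists), 13 lower in both (13.7), 6 higher with CSDS and lower with knockdown (13), and 18 lower with CSDS and higher with knockdown (9.39). The shared genes with the smallest p were Stxbp6 (-0.48 in both), the endothelial receptor gene Eng (0.55 and 0.50), the collagen gene Col6a3 (0.93 and 0.87), the diacylglycerol kinase gene Dgkh (-0.62 and -0.61) and Hba-a2 (1.57 and 1.17). Of the genes lower with CSDS and higher with knockdown, looked up after the counts were seen, those with the smallest p were Serhl (-0.73 and 0.83), Ccdc9b (-0.52 and 0.56), Lgi4 (-0.71 and 0.56) and the TGF-beta receptor gene Tgfbr2 (-0.39 and 0.40). None of these 9 genes passed over all genes in either contrast.

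A test of the difference between the 2 effects by edgeR called 0 genes, with 765 at an unadjusted p under 0.05; DESeq2 and limma-voom also called 0. Without SSDS-shACOT12 2 the count was 188. The genes with the smallest p were Serhl (difference 1.56 ± 0.35), Gm26736 (-2.81 ± 0.64), Gm6999 (3.25 ± 0.75), the secreted myelination factor gene Lgi4 (1.28 ± 0.29) and Manf (-0.69 ± 0.16), each with adjusted p = 0.920. The CSDS effect and the SSDS-GFP effect share the control libraries, which gives them a positive correlation by itself. Their correlation across genes was 0.642, against a mean of 0.502 and a maximum of 0.529 in 100 simulations with no effect; the covariance was 0.0830 against 0.0492. The 3 control libraries were not divided between the contrasts. A trait of these libraries beyond the simulated spread may therefore still give part of this excess. The simulated range was also narrow. Over 100 combinations of splits of the real libraries, the correlation of the knockdown effect with the CSDS effect had an SD of 0.143. The simulations therefore do not show that the excess goes beyond chance.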

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

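The tests below chosen only after the result was seen were the other splits of the libraries, the swap of 2 libraries, the pairs of SSDS libraries by number with the block they give, whether 1 library decides the chaperone rise, the handling or batch test, and the run with 2 libraries left out; the tests of gene length and of mitochondrial RNA were set before their result was seen.

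In 9 gene lists the knockdown effect under SSDS differed from the CSDS effect by a test of the difference itself. With an estimated correlation none of the 9 passed (smallest adjusted p = 0.875), and fry called 0. Heat shock and unfolded protein response genes had a median difference of -0.37 (knockdown effect minus CSDS effect, adjusted p = 1.2e-09) and stayed called without any 1 of the 12 libraries. Mitochondrially encoded genes had a median difference of -0.89 (adjusted p = 1.4e-06), called in all 12 such runs, and -0.43 without SSDS-shACOT12 1, -0.56 without SSDS-shACOT12 3 and -2.05 without SSDS-shACOT12 2. Ependymal genes had a median difference of 0.68 (adjusted p = 1.3e-06), called in all 12 runs, and 1.34 without CSDS 2, 0.45 without CSDS 3 and 1.14 without SSDS-GFP 1. Ribosomal protein genes had -0.21 (adjusted p = 3.3e-06), with -0.37 without SSDS-GFP 2 and -0.13 without SSDS-GFP 3, and were not called without SSDS-shACOT12 2 (-0.13, adjusted p = 0.256); with the length trend removed they had -0.13 (adjusted p = 5e-04). Nuclear oxidative phosphorylation genes had -0.14 (adjusted p = 8.4e-05), -0.23 without Control 2 or CSDS 3, -0.26 without SSDS-GFP 2, -0.29 without SSDS-shACOT12 3 and -0.09 without CSDS 2, and were not called without SSDS-GFP 1 (-0.07, 0.0914) or SSDS-shACOT12 2 (-0.08, 0.299); with the length trend removed they had -0.04 (adjusted p = 0.0165), so most of this median went with gene length.

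Blood cell genes had a median difference of -0.40 (adjusted p = 0.0030), -0.20 without Control 1, -0.72 without Control 2, -0.26 without Control 3, -0.19 without SSDS-GFP 1 and -1.50 without SSDS-shACOT12 3, and were not called without SSDS-shACOT12 1 (-0.18, adjusted p = 0.156) or SSDS-shACOT12 2 (-0.19, 0.405). Choroid plexus genes had 0.77 (adjusted p = 0.0159) and were not called without Control 1 (0.32, adjusted p = 0.207), CSDS 3 (0.48, 0.0668), SSDS-GFP 3 (0.37, 0.0615) or SSDS-shACOT12 2 (0.61, 0.123). Interferon response genes had -0.40 (adjusted p = 0.0269), -0.62 without Control 2, -0.60 without CSDS 2 and -0.61 without SSDS-GFP 2, and were not called without Control 3 (-0.25, adjusted p = 0.691), CSDS 1 (-0.36, 0.0568), CSDS 3 (-0.32, 0.269), SSDS-GFP 3 (0.16, 0.791) or SSDS-shACOT12 2 (-0.28, 0.309). Ventral hippocampus markers had -0.47 (adjusted p = 0.0427), -1.33 without SSDS-shACOT12 2, and were not called without Control 1 (-0.49, adjusted p = 0.0615), Control 3 (-0.22, 0.189), CSDS 1 (-0.38, 0.0976), SSDS-GFP 2 (-0.45, 0.0520), SSDS-GFP 3 (-0.10, 0.544), SSDS-shACOT12 1 (-0.11, 0.563) or SSDS-shACOT12 3 (-0.14, 0.0999), nor with DESeq2 size factors (adjusted p = 0.0540). With the replicate number as a block among the SSDS libraries, blood cell genes (-0.53, adjusted p = 0.0697) and ventral hippocampus markers (-0.67, 0.101) were not called and inflammatory cytokine and NF-kB genes were (-0.25, 0.0276; adjusted p = 0.852 with an estimated correlation). With SSDS-GFP 3 and SSDS-shACOT12 2 both left out, 3 of the 9 lists were called: heat shock genes (-0.46, adjusted p = 3.6e-05), mitochondrially encoded genes (-2.46, 2.7e-11) and ventral hippocampus markers (-0.73, 0.0075). Antigen presentation genes (1.14, adjusted p = 0.0224, against -0.25 with all libraries) and oligodendrocyte and myelin genes (-0.24, 0.0116) were called in that run too. Inflammatory cytokine and NF-kB genes were not (0.06, 0.667). With an estimated correlation no list was called in that run (smallest adjusted p = 0.728). No gene differed by edgeR, with 765 at an unadjusted p under 0.05, and 0 by DESeq2 or limma-voom. With a real count of 0 the 100 combinations of splits could only give as many or more (100 of 100, highest other 1125), so that comparison tests nothing. For the correlation between the effects, 83 of 100 combinations gave an absolute value at least as large as the real 0.028 (on log2 CPM; highest other 0.429), so chance is not excluded for it.

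Oxidative phosphorylation and ribosomal protein genes were higher in both CSDS and SSDS-GFP than in control, and both lists hold mostly short genes, with median lengths of 1675 and 1734 bases. With each library's trend with gene length removed, the median of the oxidative phosphorylation list went from 0.27 to 0.18 in CSDS and from 0.45 to 0.29 in SSDS-GFP, and that of the ribosomal list from 0.19 to 0.11 and from 0.42 to 0.29. At the preset correlation all 4 stayed called (adjusted p from 8.7e-18 to 1.8e-05), which argues against the length trend as the whole cause, though it may account for part. With an estimated correlation none of the 4 was called, before (adjusted p = 0.834 and 0.604 for oxidative phosphorylation in CSDS and SSDS-GFP, 0.914 and 0.604 for ribosomal proteins) or after (0.715, 0.678, 0.995 and 0.678). RNA quality was not given, a biological effect of stress stays open, and both contrasts use the same control libraries.

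Chaperone genes were higher in SSDS-GFP than in control (median 0.68). With the length trend removed the median was 0.65 (adjusted p = 8.3e-27), and with 1 of the 6 libraries left out it was at lowest 0.60 and was called each time, which argues against gene length and against 1 library as the cause. These calls are at the preset correlation; with an estimated correlation the adjusted p was 0.0584 before and 0.0447 after the trend was removed. In all 6 SSDS libraries the list score lay above that of every control and CSDS library, so SSDS, the virus given to both SSDS groups and a difference of handling or batch cannot be told apart. Of the 10 splits of control and SSDS-GFP libraries, 1, the real one, gave as many genes (16, highest other 0), and 10 gave as many lists (8, highest other 18); 10 splits are too few for a share under 0.05.

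The 6 SSDS libraries divided across their labels. SSDS-GFP 1, SSDS-GFP 2 and SSDS-shACOT12 2 against the other 3 gave 3677 genes, which points to a structure of the samples, while the real split gave 0, a count that all 10 splits must reach, so it tests nothing; all 10 gave at least the real 5 lists (highest other 21). With the length trend and mitochondrial genes removed that split still gave 3700 genes, which argues against the length trend as the cause. This run cannot decide on mitochondrial RNA, because nuclear genes that vary with it were kept. SSDS-GFP 3, SSDS-shACOT12 1 and SSDS-shACOT12 3, on 1 side of that split, had the lowest mt-Nd6 levels (272, 71.8 and 118 CPM). A swap of SSDS-GFP 3 with SSDS-shACOT12 2 may be an explanation: SSDS-GFP 3 correlated at 0.124 and 0.346 with SSDS-shACOT12 1 and 3 against -0.09 and -0.37 with SSDS-GFP 1 and 2, and SSDS-shACOT12 2 at 0.0014 and 0.253 with SSDS-GFP 1 and 2 against -0.38 and -0.21 with SSDS-shACOT12 1 and 3. The largest median difference among pairs the swap would make replicates was 0.277 (log2), against 0.202 within control and CSDS. This comparison cannot decide on the swap. Pairs that are replicates with or without the swap lay above 0.202 too: SSDS-GFP 1 with 2 (0.257) and SSDS-shACOT12 1 with 3 (0.246). The pairs that only the swap makes replicates lay between 0.198 and 0.277. The swap therefore stays open and cannot be told apart from other variation. A response to the knockdown in part of the mice, or inflammation in SSDS-GFP 3, also stays open, as neither was tested.

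A structure shared by SSDS libraries of the same number may account for part of this: with the libraries paired by number 3246 genes differed between the pairs, against 1757 in the highest of the 5 other pairings. The split with 3677 genes keeps both libraries 2 on 1 side and both libraries 3 on the other, but so does SSDS-GFP 1, SSDS-GFP 3 and SSDS-shACOT12 3 against the rest, which gave 0 genes; this goes against the number alone, which predicts many genes in both splits, and a swap predicts many only in the former. The number stays open beside other variation. On the first principal component the libraries 1 scored 5.82 and 37.4, the libraries 2 -26.5 and -11.1, and the libraries 3 35.7 and 63.1. In all 3 pairs SSDS-shACOT12 scored above SSDS-GFP, a difference that was not tested. The number together with such a difference would also give more genes in the split with 3677 than in the one with 0. These 2 splits therefore do not favour the swap over it. The correlations of deviations from the group means at the same number (0.196, 0.419 and 0.353) lay above those at other numbers (-0.38 to -0.02). Deviations from a group mean sum to 0 for each gene, so positive values at the same number force negative ones elsewhere on balance. The contrast between them is therefore no further evidence for the number. The 4 splits that part all 3 pairs, the real one among them, gave 0 genes each and 5 (real), 11, 13 and 16 lists; with the block the real one gave 0 genes and 9 lists, and the others up to 6 genes and 13 to 17 lists.

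For CSDS against control the real count of 0 genes is one that all 10 splits must reach (highest other 0), so it tests nothing, and 8 gave at least the real 10 lists (highest other 16); 10 splits are too few for a share under 0.05.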

How the results depend on the processing

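The replicate number as a block among the SSDS libraries, quality weights, leaving out mitochondrial genes, removing the length trend and leaving out SSDS-GFP 3 with SSDS-shACOT12 2 were alternatives chosen after seeing the data. In CSDS against control edgeR called 0 genes under DESeq2 size factors, a filter of 50 counts, the length trend removed or mitochondrial genes left out, but DESeq2 called 6, no filter 132, the 6 libraries alone 84 and quality weights 34; with 1 library left out the count was 0 to 1. For knockdown the count of 0 became 108 with no filter and 2947 without the 2 libraries, and 0 to 985 with 1 library left out. For SSDS-GFP against control the 16 genes became 10 with a log2 fold change of at least 1, 527 with DESeq2 (15 of the 16 shared), 608 with no filter, 34 on the 6 libraries alone, 9 with the replicate number as a block, 2239 with quality weights, 57 without the 2 libraries, and 4 to 15 with 1 library left out; a filter of 50 counts gave 16 (15 shared) and FPKM gave 12. The difference of effects went from 0 to 70 with no filter, 1562 without the 2 libraries and 0 to 188 with 1 library left out. The lists called (10, 5 and 8) fell to 0, 0 and 0 with an estimated correlation and to 0, 0 and 1 with fry, were 10 for knockdown on its 6 libraries alone and 9 with the replicate block among the SSDS libraries, and with 1 library left out ran from 9 to 12, 4 to 14 and 9 to 12. With that block knockdown still gave 0 genes, with 2579 at an unadjusted p under 0.05, and the difference of effects 0, with 2082; the block over all 12 libraries gave 10, 6 and 9 lists. The block among the SSDS libraries changed no call of a gene or list in the knockdown contrast or the difference other than those given. Of the 12 libraries 4 correlated best with one of their own number, a share that numbers given at random would also give. The correlation of the effects stayed near 0, from -0.051 to 0.118 with 1 library left out. Fewer samples and fewer genes tested follow from leaving out libraries and from filters; for the other settings the cause was not tested.

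Among named genes the direction held under DESeq2 size factors and the DESeq2 test, except that Aif1 with knockdown went from 0.0037 to -0.0031 under both. With 1 library left out the sign changed in CSDS against control for Acot12 (-0.18 to 0.28), Il1b (-0.71 to 0.63), Cd68 (-0.23 to 0.11), Nlrp3 (-0.50 to 0.61), Tlr4 (-0.68 to 0.23), Bdnf (-0.30 to 0.19) and Fkbp5 (-0.29 to 0.0071). With knockdown it changed for Rsad2 (-2.58 to 0.18), mt-Co3 (-2.76 to 0.14), Il1b (-3.98 to 3.74), Aif1 (-0.20 to 0.14), Itgam (-0.31 to 0.21), Nlrp3 (-0.59 to 0.72), Bdnf (-0.24 to 1.15), Fos (-0.36 to 0.86) and Fkbp5 (-0.070 to 0.19), and in SSDS-GFP against control for Ccl5 (-1.34 to 7.28). None of these genes passed with all libraries, and the cause was not tested.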

Other observations

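Immune transcripts were abundant in SSDS-GFP 3, which was singled out after its values were seen. Ccl5 was at 79.5 CPM, Ccl22 at 68.6, Cd74 at 48.0, Il1b at 13.5, Tnf at 12.5, H2-Aa at 12.5 and Il6 at 7.32 CPM in that library. Its Tnf and Il6 counts were 219 and 128. SSDS-shACOT12 3 had 16.3 CPM of Ccl22 and 7.06 CPM of Ccl5, beside 1192 CPM of Gfap. Trh, which encodes thyrotropin-releasing hormone, was at 29.9 CPM in SSDS-shACOT12 2.

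Gapdh, a glycolytic enzyme gene with many pseudogenes, took low and high values within every group. It was at 10.9, 162 and 10.4 CPM in control, 364, 9.52 and 9.06 in CSDS, 121, 9.78 and 361 in SSDS-GFP, and 13.1, 309 and 14.8 in SSDS-shACOT12. No test of the cause was made, and Gapdh is not used here as a reference gene.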
